A study of Canis lupus familiaris with 9 samples.

How the data were processed

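Total RNA from the placentae of 9 bitches was sequenced, 1 library per animal, in 3 groups of 3. The libraries were made with an Illumina TruSeq RNA kit from Trizol-extracted RNA, per the labels' protocols. Per the submitters' processing notes, the tools used were STAR, a spliced read aligner, and featureCounts, which counts aligned reads per gene, with the dog genome build CanFam3.1. Their versions, settings and strand mode, and the annotation release, are not given in the sources used here. If reads were counted without strand, those of overlapping and antisense genes cannot be told apart, and genes with near-identical copies can share reads.

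The authors deposited 1 table of raw read counts per library, with a whole-number count for each of 24580 Ensembl dog gene identifiers and no normalization. All 9 tables listed the same identifiers in the same order, with no duplicates and no entry for unassigned reads. Of these identifiers, 18841 had at least 1 count in at least 1 library.

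The count tables give identifiers without gene symbols. The reference table available here lists 43286 dog genes of another assembly, UU_Cfam_GSD_1.0, and holds no Ensembl identifiers, so 0 of the 24580 identifiers matched a symbol. For that reason no gene is named. The 30 gene lists fixed for this tissue, which covered prostaglandin, steroid, matrix, immune and vascular genes and markers of the cell types a placental sample can hold, were written by symbol and could not be tested. The rule for named genes also asked for symbols and named none. It asked for genes called in a contrast, with a mean log2 CPM of at least 1 over the 9 libraries, with no overlap between the 3 libraries of one group and the 3 of the other, and with the 10 largest positive and 10 largest negative log2 fold changes, for the leading members of each list, for preset genes of progesterone, prostaglandin and related signalling, and for the leading genes called in both contrasts against mid-gestation. In place of these, 3 identifiers are printed, chosen after their values were seen as the extremes of the first part of that rule without the symbol condition, in the contrasts that had calls. No coordinates are given, because no annotation of CanFam3.1 was used here.

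Groups were taken from the source name of each sample. Replicate numbers within a group follow accession order and pair no samples. The groups, the tests and the first set of alternatives below were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 14049 genes. Library sizes were scaled by the trimmed mean of M values (TMM). A quasi-likelihood negative binomial model with one mean per group was fitted to all 9 libraries together, with robust estimation, so that the 3 contrasts shared one estimate of the spread. Each contrast was tested two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 14049 genes. A gene was called when its adjusted p was under 0.05. Fold changes are log2 values from that fit. Their standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. Levels are in CPM, each gene's count scaled by its library's TMM-adjusted total. The animals were separate bitches, so the spread within a group is between animals.

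Library similarity was measured with Spearman correlations and principal components of log2 CPM over the 14049 genes. Counts of library pairs were compared by chi-square over genes with at least 10 counts in the pair. Numbers of detected genes were also computed at an equal depth of 17519437 counts by rarefaction. In all, 6 measures of library make-up were compared between groups by exact permutation tests, two-sided, 18 tests in all, adjusted by the Benjamini-Hochberg method. With 3 animals against 3, such a test cannot give a p under 0.1.

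The procedure was tested on simulated counts drawn from the mean levels and library sizes of these libraries and one dispersion per gene for all groups, with 100 genes changed 2-fold and 100 changed 4-fold. For prepartum minus mid-gestation, 55 of the 100 genes changed 4-fold and 1 of the 100 changed 2-fold were called, over 13793 genes tested, and 3 of 59 calls were false. For antigestagen minus mid-gestation, 57 and 2 of 100 were called over 13803 genes, and 6 of 65 calls were false. For antigestagen minus prepartum, 56 and 2 of 100 were called over 13807 genes, and 3 of 61 calls were false. The shares recovered hold for that number of changed genes, since the adjusted p is less strict where more genes change. Totals per library ran from 17519437 to 26952764 counts.

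Both contrasts against mid-gestation use the same 3 mid-gestation libraries. Likewise, prepartum minus mid-gestation and antigestagen minus prepartum share the prepartum libraries. The agreement of such contrasts is therefore given beside 20 simulated data sets with no group changed, and 20 in which prepartum changed as fitted and the antigestagen group did not change. Every library, mid-gestation included, was drawn anew in each data set. The same simulations were also run without mid-gestation replicate 3. The alternatives set beforehand were DESeq2 1.42.0, RLE size factors (median of ratios) in place of TMM, no filter on low counts, a filter of 1 CPM in at least 6 libraries, a fit of only the 6 libraries compared, an adjusted p under 0.01, a test against a fold of 1.5 (glmTreat), and leaving out each library in turn. The alternatives chosen after seeing the data were limma-voom 3.58.1 with sample quality weights, leaving out mid-gestation and antigestagen replicate 3 together, and thinning all libraries to equal depth. Groups of 3 are too small for a test of single outlying libraries. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.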

Results

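Gene expression was measured by RNA sequencing in the placentae of 9 healthy cross-bred bitches, collected at ovariohysterectomy. Of these, 3 were in mid-gestation, at days 35 to 40 after mating, and 3 were at the natural prepartum luteolysis, the fall in progesterone that precedes birth. In the latter, serum progesterone was followed every 6 h from day 58, and tissue was taken once 3 consecutive values were below 3 ng/ml. The other 3 had abortion induced in mid-pregnancy with the antigestagen aglepristone, which blocks the progesterone receptor. They received 10 mg/kg, 2 times at an interval of 24 h, and tissue was taken 24 h after the last dose. The design addresses how placental expression changes when progesterone signalling ends naturally and when it is blocked. The prepartum group was also later in gestation than the other groups, so stage and luteolysis change together in any contrast with it. No day of gestation was recorded here for the antigestagen group, so its match in stage to mid-gestation cannot be checked.

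The libraries held between 17519437 counts (antigestagen replicate 2) and 26952764 counts (antigestagen replicate 3). Totals ran from 21318365 to 25532844 in mid-gestation and from 24362227 to 26759623 in prepartum libraries. Between 14497 and 16977 genes had at least 1 count. At an equal depth of 17519437 counts, 16218 ± 399 genes were detected in mid-gestation, 15750 ± 197 in prepartum and 15647 ± 1049 in antigestagen placentae (SD, n = 3). Antigestagen replicate 2 was the shallowest library and detected the fewest genes, 14497. These numbers did not separate the groups by exact permutation tests, two-sided (p = 0.3 for prepartum against mid-gestation, adjusted p = 0.675, the lowest of the 3 comparisons).

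The counts of prepartum placentae were concentrated on fewer genes than those of the other groups. The 10 most abundant genes took 27.2% ± 3.71 of all counts in prepartum libraries, against 17.2% ± 3.24 in mid-gestation and 17.1% ± 1.08 in antigestagen libraries (SD, n = 3). The most abundant gene was the same in all 9 libraries, and it took 7.42% ± 0.245 of counts in prepartum, 4.30% ± 1.17 in mid-gestation and 3.86% ± 0.423 in antigestagen libraries. The most abundant genes that together reached 50% of counts numbered 158 ± 52.8 in prepartum, 407 ± 134 in mid-gestation and 347 ± 68.0 in antigestagen libraries. For all 3 measures the 3 prepartum libraries lay beyond every library of the other groups. Against either other group, each exact permutation test, two-sided, gave p = 0.1 (n = 3 per group), the smallest that 3 against 3 allows, and 0.3 after adjustment over 18 tests. All 10 of the most abundant genes were common to the 3 prepartum libraries, against 7 in mid-gestation and 8 in the antigestagen group, and 4 were common to all 9 libraries. Of the 16 genes that reached the top 10 of any library, 2 passed the gene-level test between prepartum and mid-gestation, both higher in prepartum.

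The first principal component of log2 CPM, with 33.9% of the variance, placed the 3 prepartum libraries at 50.6 to 72.0 and the other 6 at -85.9 to -1.52. The second component, with 19.4%, placed antigestagen libraries at 6.62 to 60.7 and mid-gestation libraries at -70.6 to 0.638. Prepartum placentae were the most alike, with a mean Spearman correlation of 0.967 ± 0.0124 over 3 pairs, against 0.955 ± 0.0113 for antigestagen and 0.930 ± 0.0096 for mid-gestation placentae (SD over pairs that share libraries). The biological coefficient of variation over all tested genes was 0.320 in prepartum, 0.393 in antigestagen and 0.478 in mid-gestation placentae. Mid-gestation replicate 3 and antigestagen replicate 3 formed the most similar of all 36 pairs (0.978). The mean correlation of mid-gestation replicate 3 with its own group was 0.933, below its means of 0.951 with the antigestagen and 0.944 with the prepartum group. Its own-group mean was still the highest of the mid-gestation libraries, with 0.924 for replicate 1 and 0.931 for replicate 2. Replicate 1 was also closer to the antigestagen group (0.930) than to its own, while replicate 2 was not (0.921). With antigestagen replicates 1 and 2 alone, the mean of mid-gestation replicate 3 was 0.937. No libraries held identical counts, and the lowest chi-square per degree of freedom of any pair was 62.5, so none was treated as a repeat of another.

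**Figure D1:**
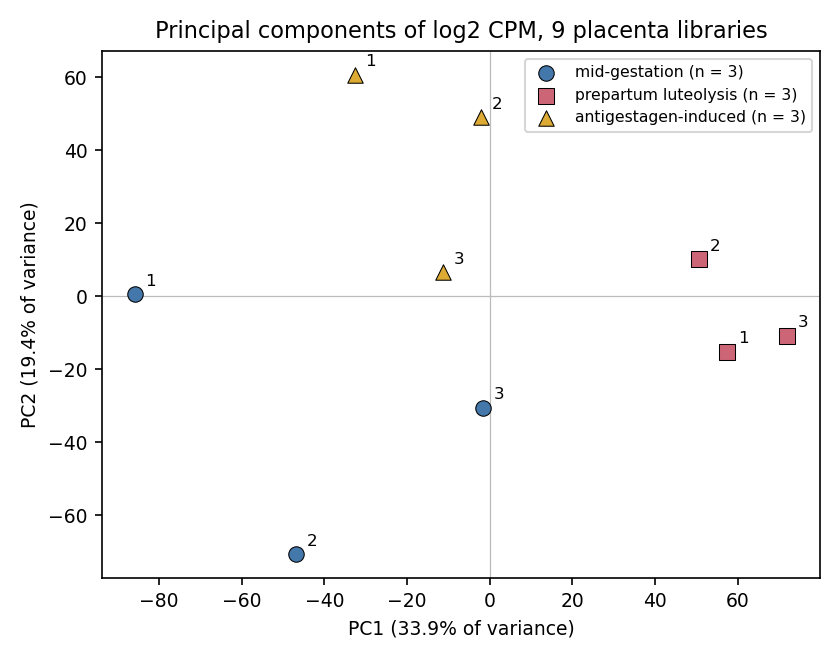
Scores of the 9 placenta libraries on the first principal component (x axis, 33.9% of variance) and the second (y axis, 19.4%) of log2 CPM over 14049 genes; each point is 1 library, numbered by replicate, and colour and shape give the group. The 3 prepartum libraries lie at 50.6 to 72.0 on the first component. Mid-gestation replicate 3 lies at -1.52 on it, and antigestagen replicates 2 and 3 lie at -2.11 and -11.2.

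**Figure D2:**
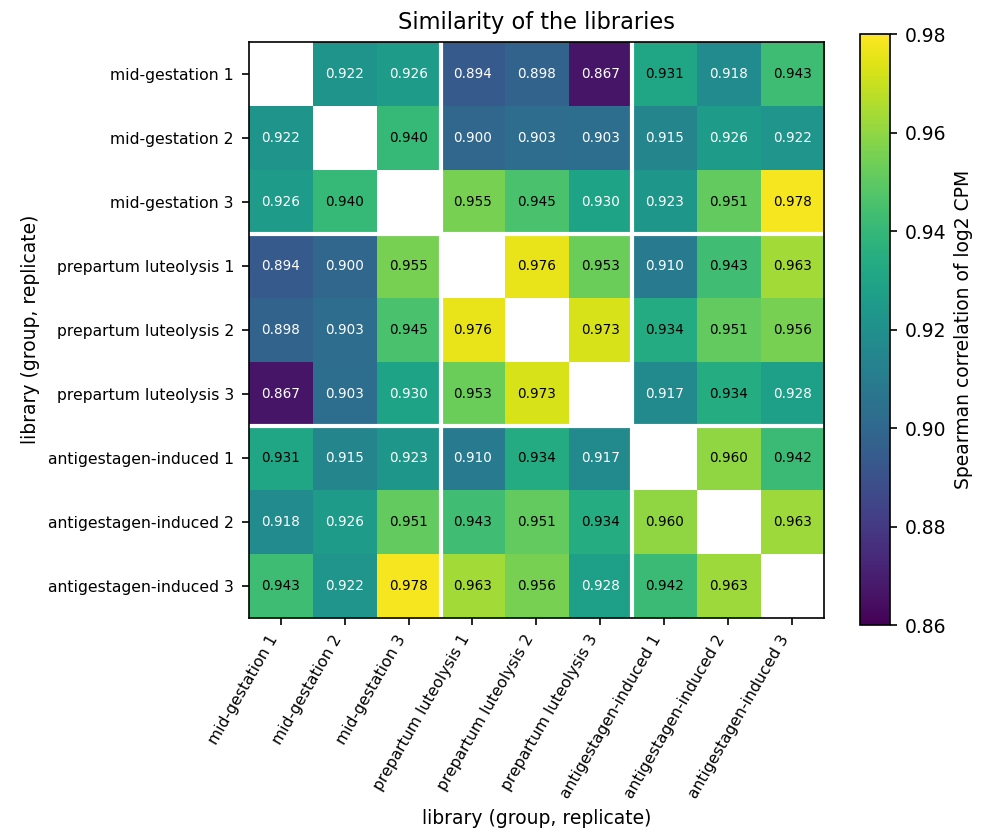
Spearman correlation of log2 CPM (colour and printed value) between each pair of libraries, which are on both axes in group order. The highest of the 36 values, 0.978, is between mid-gestation replicate 3 and antigestagen replicate 3, and the lowest, 0.867, is between mid-gestation replicate 1 and prepartum replicate 3.

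The first contrast asked what differs at natural luteolysis from mid-gestation. Of 14049 genes, 799 changed, 409 higher and 390 lower in prepartum placentae, with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Data simulated with one dispersion per gene for all groups gave calls for 55 of 100 genes changed 4-fold and for 1 of 100 changed 2-fold, while the real mid-gestation libraries varied more than the others. Those data gave 59 calls, against 799 here. The adjusted p is less strict where more genes change, so these shares do not give the power of the real contrast. The higher genes had a median log2 fold change of 1.77 (quartiles 1.32 and 2.35), and the lower genes one of -1.85 (quartiles -2.56 and -1.40). At least a 4-fold change was seen in 154 of the higher and 166 of the lower genes, and only 13 and 23 changed less than 2-fold. In 797 of the 799 genes the 3 prepartum libraries did not overlap the 3 mid-gestation libraries, a separation that chance gives for 10% of genes and that 30.2% of all tested genes showed.

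By mean level over all 9 libraries, more of the higher than of the lower genes were abundant. That level includes the prepartum libraries, so the change itself moves higher genes up and lower genes down, which favours this split. Among the most abundant of 3 equal classes of genes, 204 rose and 117 fell, while in the least abundant class 70 rose and 109 fell. The 409 higher genes took 4.02% ± 1.70 of counts in mid-gestation libraries and 14.0% ± 1.60 in prepartum libraries, and the 390 lower genes took 2.94% ± 0.787 and 0.605% ± 0.0341 (SD, n = 3). These genes were chosen on the same libraries, so the shares describe their weight and are not a test. In antigestagen libraries the shares lay between, at 7.36% ± 0.686 and 1.72% ± 0.0214.

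Among called, non-overlapping genes with a mean log2 CPM of at least 1, the largest rise was that of ENSCAFG00000032326. It went from a low level of 0.771 ± 0.525 CPM in mid-gestation (10 to 28 counts per library) to 47.1 ± 37.8 CPM in prepartum placentae (SD, n = 3). Its log2 fold change was 5.96 (SE 0.84) with an edgeR adjusted p of 0.00987. It was 5.07 without prepartum replicate 2, at 90.5 CPM the highest library, and 6.63 without mid-gestation replicate 2, and the call held without any single library of this contrast. The largest fall was that of ENSCAFG00000000696, with a log2 fold change of -6.77 (SE 1.57) and an edgeR adjusted p of 0.0412. Its level was 2.13 ± 1.61 CPM in prepartum placentae and 233 ± 341 CPM in mid-gestation, where the 3 libraries ranged from 9.20 to 626 CPM. Without mid-gestation replicate 1, the highest of them, the log2 fold change was -4.08, and without prepartum replicate 2 it was -7.45. Its call was lost without mid-gestation replicate 2 (edgeR adjusted p = 0.0522) and without prepartum replicates 1, 2 or 3 (0.155, 0.130 and 0.164), and over all 16 alternatives the adjusted p ran from 2.08e-05 to 0.164. The gene ENSCAFG00000013625 fell from 113 ± 31.9 to 2.68 ± 1.67 CPM, with a log2 fold change of -5.39 (SE 0.66) and an edgeR adjusted p of 0.00628. Its call held in all 16 alternatives, with adjusted p up to 0.0312, and the log2 fold change ran from -5.71 to -4.93.

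The count of changed genes depended on single animals. It was 383 without mid-gestation replicate 1, 340 without replicate 2 and 1240 without replicate 3. It was 451, 75 and 335 without prepartum replicates 1, 2 and 3. None of the 799 genes changed sign in these fits. That was largely fixed in advance, since 797 of them had no overlap between the groups.

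**Figure D3:**
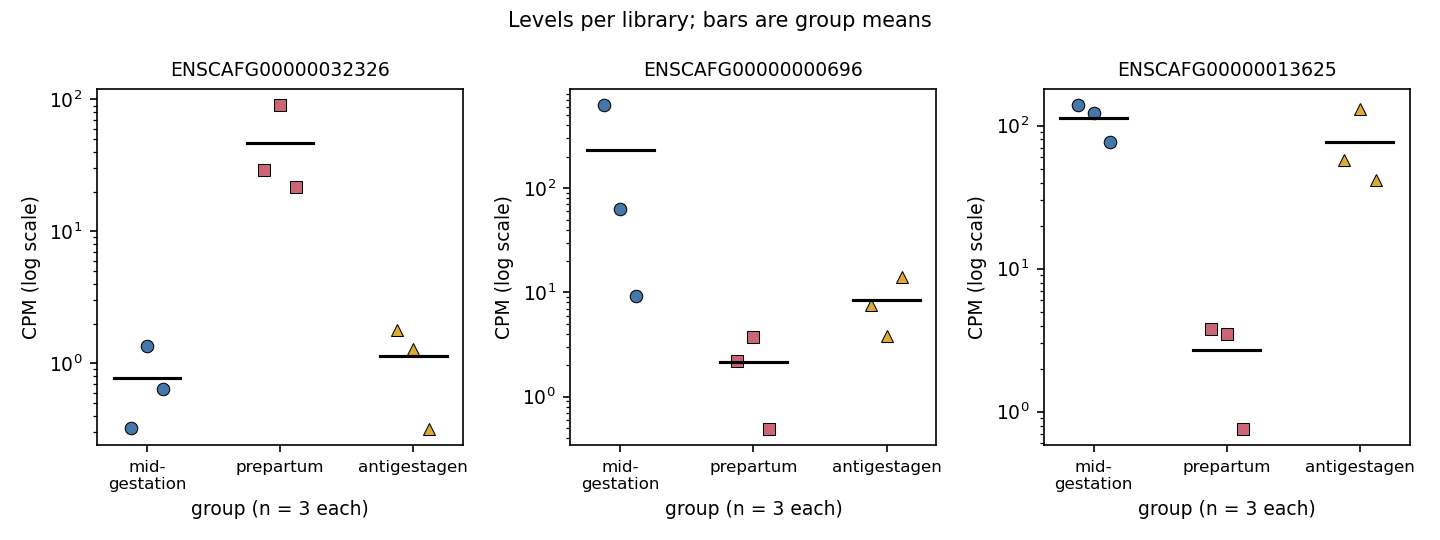
Level in CPM (y axis, log scale) of 3 genes in each library, by group (x axis, n = 3 each); points are libraries and bars are group means. ENSCAFG00000032326 is at 21.8 to 90.5 CPM in prepartum placentae and at most 1.79 CPM in all others, while ENSCAFG00000013625 is at 0.759 to 3.80 CPM in prepartum placentae and at least 41.8 CPM in all others.

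The second contrast asked what differs from mid-gestation after the progesterone receptor was blocked in mid-pregnancy. No gene passed in antigestagen against mid-gestation placentae with edgeR's quasi-likelihood test, and the lowest adjusted p was 0.345. At an unadjusted p under 0.05 there were 1304 genes, 713 higher and 591 lower, where 702 would be reached by chance among 14049. This excess depended on single animals. The number was 639 of 14366 genes without antigestagen replicate 2, fewer than chance gives, and 944 and 2207 without antigestagen replicates 1 and 3. It was 1419, 899 and 1859 without mid-gestation replicates 1, 2 and 3, and 928 in a fit of only these 6 libraries. DESeq2 called 146 genes, 82 higher and 64 lower, and limma-voom with sample quality weights called 0. Without mid-gestation replicate 3, edgeR called 130 genes, 90 higher and 40 lower. Of these 130, 119 were also called in the same direction between prepartum and mid-gestation in that fit, where 5.81 would overlap if the lists were independent. Both lists use the same mid-gestation libraries. Simulated without that library, an unchanged antigestagen group beside a changed prepartum group gave 0 to 3 calls, of which 0 to 2 were such genes, over 20 draws. That simulation had one dispersion per gene for all groups, so it leaves out the wider spread of the real mid-gestation libraries. Leaving out any of the other 5 libraries of this contrast gave 0 calls. With one dispersion per gene for all groups, the simulated test recovered 57 of 100 genes changed 4-fold and 2 of 100 changed 2-fold.

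Genes that changed at natural luteolysis tended to be displaced the same way in the antigestagen group. Of the 409 genes that were higher in prepartum placentae, 395 (96.6%) had a positive log2 fold change between antigestagen and mid-gestation, with a median of 0.77. Of the 390 lower genes, 346 (88.7%) had a negative one, with a median of -0.49. With an unchanged antigestagen group and simulated mid-gestation libraries shared by both contrasts, the shares were 65.1% (61.9 to 67.8 over 20 draws) and 65.6% (63.5 to 69.1). They cover the genes called in each draw, 1884 on average. The simulated medians were 0.17 and -0.18. The simulated lists were longer than the real one of 799 genes, so their shares and medians are not a like-for-like reference. On the log2 CPM scale the antigestagen group stood at a median of 0.458 of the distance from mid-gestation to prepartum for the higher genes and 0.250 for the lower genes. These genes were chosen on the same mid-gestation libraries, and no simulated reference was computed for the positions.

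Over all 14049 genes, the log2 fold changes of both contrasts had a Pearson correlation of 0.538 across genes, which are not independent replicates. With simulated mid-gestation libraries shared by both contrasts, it was 0.496 (0.481 to 0.518) with no group changed. It was 0.228 (0.205 to 0.253) with prepartum changed as fitted and the antigestagen group unchanged. The covariance was 0.369, against 0.142 in both simulations (0.136 to 0.150 and 0.124 to 0.158). The simulation used one dispersion per gene for all groups, and the mid-gestation libraries varied more than the others. The prepartum change as fitted also holds sampling noise, to which each draw adds more. Those draws called 1884 genes on average against the real 799, so 0.228 is not a like-for-like reference. With the variance of the mid-gestation mean measured from those libraries themselves, the covariance of mean log2 CPM differences was 0.353, of which the controls accounted for 0.188, and the difference was 0.165. That difference was 0.0315 without mid-gestation replicate 2 and 0.317 without replicate 3, and 0.129 to 0.188 without any other library. The 3 controls cannot be split into 2 sets of at least 2, so part of the same-sign excess may come from the shared controls.

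**Figure D4:**
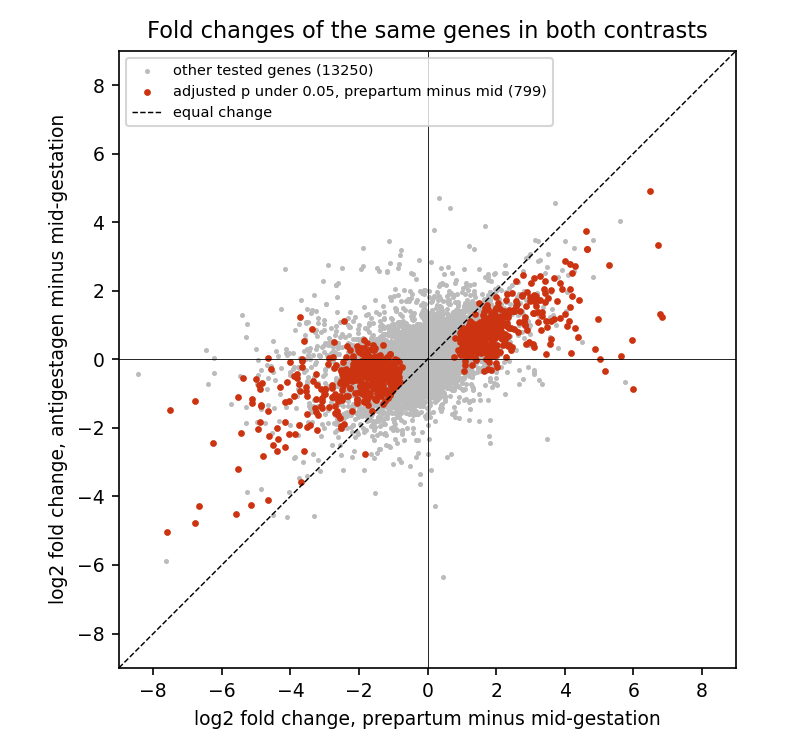
Log2 fold change of each tested gene in prepartum minus mid-gestation (x axis) and antigestagen minus mid-gestation (y axis); red points are the 799 genes called in the former, grey points are all other tested genes, and the dashed line marks equal change. Red points lie mostly on the same side of 0 on both axes and nearer 0 on the y axis, with medians of 0.77 and -0.49; both axes share the mid-gestation libraries.

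The third contrast compared progesterone receptor blockade in mid-pregnancy with natural luteolysis directly. Between antigestagen and prepartum placentae 90 genes changed, 69 higher and 21 lower in the antigestagen group, with edgeR's adjusted p under 0.05. The median log2 fold change was 1.95 for the higher and -1.96 for the lower genes. Of the 90, 83 (92.2%) had also changed between prepartum and mid-gestation, all toward mid-gestation in the antigestagen group. Both contrasts use the prepartum libraries, which sets this direction largely by construction, and 5.12 would overlap if the lists were independent. Simulation with no group changed gave 0 calls between antigestagen and prepartum. With prepartum changed as fitted and the antigestagen group left at mid-gestation levels, 69.2% of such calls overlapped (66.8 to 71.7 over 20 draws), all in that same direction. The simulated lists held 1874 calls on average (1762 to 1980), far more than the 90, so the simulated share is not a like-for-like reference. Between antigestagen and mid-gestation, 19 of the 90 genes (21.1%) had an unadjusted p under 0.05, against 9.28% of all tested genes. The 69 higher genes had a median log2 fold change of -0.06 between antigestagen and mid-gestation (quartiles -0.26 and 0.26). The 21 lower genes had one of 0.43 (quartiles -0.35 and 0.92).

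The share of higher genes among these calls, 76.7% with edgeR, depended on the fit. DESeq2 called 404 higher and 326 lower, limma-voom 531 and 317, and an edgeR fit of only these 6 libraries 168 and 115. In the edgeR fit of all 9 libraries, of the 390 genes lower in prepartum than in mid-gestation placentae, 66 were higher in the antigestagen than in the prepartum group. Of the 409 genes higher in prepartum placentae, 17 were lower in the antigestagen group. The gene ENSCAFG00000013625 was 4.83 higher on the log2 scale (SE 0.64) in antigestagen than in prepartum placentae, with an edgeR adjusted p of 0.0312. Its level was 76.5 ± 47.3 CPM there and 113 ± 31.9 CPM in mid-gestation (SD, n = 3), a log2 difference of -0.56 (SE 0.54) that did not pass edgeR's test (adjusted p = 0.768). The gene ENSCAFG00000032326 had a log2 fold change of -5.40 (SE 0.82) between antigestagen and prepartum placentae, with an edgeR adjusted p of 0.0370. Its level in antigestagen placentae was 1.13 ± 0.745 CPM. With single libraries left out, both calls held only without prepartum replicate 1 (edgeR adjusted p = 0.0426 for ENSCAFG00000013625 and 0.0437 for ENSCAFG00000032326). Without any other library of the contrast the adjusted p was 0.0553 to 0.113 for the former and 0.0799 to 0.136 for the latter. The log2 fold change of the former was 4.19 without antigestagen replicate 2, and that of the latter was -4.52 without prepartum replicate 2.

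The count of 90 rested on the full set of animals. It was 35, 0 and 0 without prepartum replicates 1, 2 and 3, and 4, 0 and 1 without antigestagen replicates 1, 2 and 3.

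**Figure D5:**
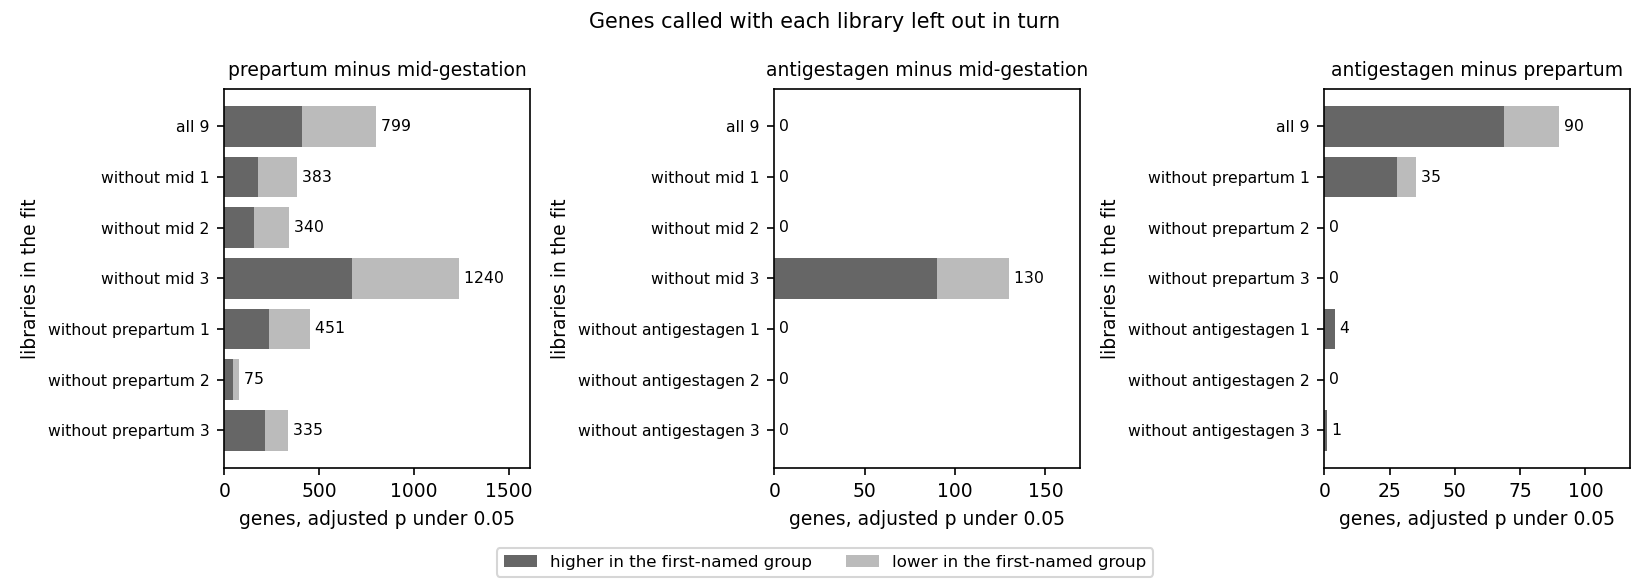
Number of genes with adjusted p under 0.05 (x axis) in each contrast with all 9 libraries and with each library of that contrast left out in turn (y axis); dark and light bars are genes higher and lower in the first-named group. The counts run from 75 to 1240 for prepartum minus mid-gestation, are 0 except without mid-gestation replicate 3 (130) for antigestagen minus mid-gestation, and run from 0 to 90 for antigestagen minus prepartum.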

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

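The tests with limma-voom, at equal depth and without both replicates 3 were chosen after the results were seen. For prepartum minus mid-gestation, where 799 genes were called, DESeq2 called 1844, limma-voom with quality weights 1636, a fit of only the 6 libraries 416, the test against a fold of 1.5 called 251, and an adjusted p under 0.01 left 48. The range with 1 library left out was 75 to 1240. Of the 799 genes, 796 were among DESeq2's calls and 767 among limma-voom's, and in none of the 16 alternatives did a called gene change sign. The limma-voom fit gave prepartum replicate 2 a quality weight of 5.498, and the next highest was 1.193, for prepartum replicate 1. Without prepartum replicate 2, edgeR called 75 genes here and 0 between antigestagen and prepartum. The limma-voom counts for both contrasts therefore weigh that animal most, and limma-voom without weights was not tested. For antigestagen minus mid-gestation, where 0 were called, DESeq2 called 146, leaving out both replicates 3 gave 57, and the range with 1 library left out was 0 to 130. For antigestagen minus prepartum, where 90 were called, DESeq2 called 730, limma-voom 848, the 6-library fit 283, the filter of 1 CPM in at least 6 libraries 151 and no filter 136. The test against a fold of 1.5 left 3, leaving out both replicates 3 left 2, an adjusted p under 0.01 left 0, and the range with 1 library left out was 0 to 35. Genes called the same way in both contrasts against mid-gestation numbered 0 in the full fit, 98 with DESeq2, 55 without both replicates 3, and 0 to 119 with 1 library left out. The correlation of fold changes, 0.538, ranged from 0.412 to 0.696 with 1 library left out and otherwise moved by less than the SD of those values. Except where fewer libraries or a stricter threshold set the count, the cause was not tested. RLE size factors called 788, 0 and 93 genes in the 3 contrasts, and equal depth 748, 0 and 102. Of the printed genes, ENSCAFG00000032326 kept its call against mid-gestation in 16 of 16 alternatives (adjusted p up to 0.0374). It kept that against prepartum in 8 of 16 (up to 0.136), ENSCAFG00000013625 did so in 8 of 16 (up to 0.113) and against mid-gestation in 16 of 16 (up to 0.0312), and ENSCAFG00000000696 kept its call against mid-gestation in 7 of 16 (up to 0.164). No paired analysis was possible because the replicate numbers follow accession order and pair no animals. The planned tests of gene lists and symbols were not run, since no identifier matched a symbol.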

Other observations

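The test of all 280 groupings, that of the highest-count genes, that of pairs of prepartum libraries, the splits and the covariance test were set out before their results were seen. The other tests below were chosen after. Over all 280 ways of dividing the 9 libraries into 3 groups of 3, the real groups gave the highest pseudo-F of log2 CPM distances, 2.34, against 2.27 for the next (exact permutation p = 0.00357, the smallest these groupings can give). This argues against profiles unrelated to the labels, and does not say which of the 3 groups differ. Mid-gestation libraries were not closer to each other (mean Spearman correlation 0.930) than to antigestagen libraries (0.934). Prepartum pairs (0.967) and antigestagen pairs (0.955) were closer than prepartum with antigestagen libraries (0.937). The covariance of both contrasts against mid-gestation exceeded what the shared libraries give by 0.165, and by 0.0315 without mid-gestation replicate 2, its lowest value with any library left out. This argues against the shared libraries as the only reason for the covariance, but the margin without replicate 2 was small, and only 3 libraries estimate the variance of the mid-gestation mean.

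In the 10 splits of the 6 prepartum and mid-gestation libraries, 1 gave as many as the 799 genes of the real one, and the highest of the others called 0. In the 10 splits of antigestagen and prepartum libraries, 1 gave as many as the real 90, and the highest other called 0. For antigestagen and mid-gestation, 10 of 10 splits gave at least the real 0, and the highest called 1. With 10 splits the share cannot fall under 0.05.

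Mid-gestation replicate 3 and antigestagen replicate 3 were the most alike of the 36 pairs, across groups. A single library deposited 2 times is argued against by a chi-square per degree of freedom of 62.5, where repeat counts of 1 library would give a value near 1 and the closest pair within a group had 63.2. Sampling noise of genes with few counts is argued against too, since the pair kept rank 1 among the third of genes with the highest counts. An exchange of both labels cannot be decided by antigestagen replicate 3. Its mean correlation was higher by 0.0197 with its own group than with mid-gestation replicates 1 and 2 (SD within a set 0.0145, 2 values each). The sets overlapped, since it correlated at 0.9427 with mid-gestation replicate 1 and at 0.9419 with antigestagen replicate 1. Whether mid-gestation replicate 3 alone carries a wrong label cannot be told apart from a true likeness between animals, which stays open as untested. Its mean correlation with its own group differed by only -0.00387 from that with antigestagen replicates 1 and 2 (SD 0.0156), and both groups were collected in mid-pregnancy.

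Far fewer genes passed in the antigestagen than in the prepartum contrast with mid-gestation. The lower depth of antigestagen replicate 2 is argued against as the reason, since with all libraries thinned to its total the prepartum contrast still called 748 genes. Equal changes hidden by a larger spread among antigestagen libraries are argued against as well: the SD of log2 fold changes across genes was 0.642 times that of the prepartum contrast, and 0.591 to 0.881 times with any library left out, where added spread would raise it. Mid-gestation replicate 3 alone is argued against too, since without it 130 genes were called in the antigestagen and 1240 in the prepartum contrast. The later stage of the prepartum group stays open as untested.

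The prepartum contrast lost most calls without prepartum replicate 2, falling from 799 to 75. Fewer libraries in the fit cannot be the whole reason, since leaving out replicate 1 or 3 left 451 and 335. The median size of the fold changes over the 799 genes was 1.78 without replicate 2 and 1.79 with it. This median cannot decide whether replicate 2 alone carries the changes. The genes were called with it included, and in 797 of them all 3 prepartum libraries lay apart from mid-gestation. The first principal component, computed without group labels, placed prepartum replicates 1 and 3 at 57.5 and 72.0. Replicate 2 lay at 50.6 and the other groups at -85.9 to -1.52. Without replicate 2, 75 genes were still called. These values argue against replicate 2 alone carrying the changes. Replicate 2 lying between the others, so that its removal raises the spread, is consistent with the biological coefficient of variation of replicates 1 and 3, the highest of the pairs at 0.378. It does not account for the other counts, since replicates 1 and 2, with the lowest value, 0.263, gave 335 calls, and replicates 2 and 3, with 0.287, gave 451. The spread of the prepartum libraries is therefore not the only factor.

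The 130 genes called between antigestagen and mid-gestation placentae without mid-gestation replicate 3 had a median absolute log2 fold change of 2.59 there. With replicate 3 included, 129 of them were tested, 96 had an unadjusted p under 0.05, and the median was 1.65. Of the 130, 51 were among the 799 genes of the full prepartum contrast. DESeq2's 146 genes included 72 of the 799.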
